A study of Homo sapiens with 18 samples.

How the data were processed

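Total RNA of HeyA8 and PC3 cells, transfected for 48 h with 10 nM of sNT8, sG5C or sCAG, was sequenced in 18 libraries, 3 for each of 6 groups. Per the labels' protocols, the RNA was made with a column kit with DNase digestion and the libraries with a kit for total RNA. Per the submitters' processing notes, reads were aligned to hg38 with TopHat and Bowtie2, counted per gene with HTSeq, and compared with DESeq2. No versions of these tools and no strand setting are given in the sources used here, so values of genes that overlap another gene on the opposite strand are uncertain, as are those of genes with near-identical copies.

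The authors deposited 4 tables of 58395 genes, each for 1 short RNA and its sNT8 libraries in 1 cell line. Per the file headers, each deposited table holds a signal, here counts divided by DESeq2 size factors, for 6 libraries. The deposited tables also hold the authors' log2 fold change with its standard error and the authors' p-value with its adjusted p. Within each library column, 100 percent of the values were whole multiples of a single step within a tolerance of 1e-06, and dividing by the step gave whole reads. For 3 libraries, HeyA8 sNT8 B, HeyA8 sG5C A and PC3 sNT8 C, the step lay within 1.2 percent of 1 in at least 1 table. The reads recovered for the sNT8 libraries were identical for all 58395 genes in both tables that hold them. The totals ran from 31232377 to 41384838 reads. Pairs of replicates differed with a chi-square per degree of freedom of 3.29 to 7.26, which is more than counting noise.

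The comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The design set edgeR on counts as the test of each short RNA against sNT8, and limma if the tables held no counts. Since the tables hold normalized values, limma 3.58.1 was used (limma-trend with robust variances, log2 of the value plus a pseudocount of 1, the 6 libraries of 1 table, filterByExpr with a count minimum of 10). Folds of genes with low values depend on the pseudocount, and all folds compare means on the log scale, so they can differ from the ratio of the printed means. The direct comparisons of sCAG with sG5C and the difference between the cell lines need values from more than 1 table. They were fitted with edgeR 4.0.16 on the recovered reads (TMM scaling, quasi-likelihood F test) of 9 libraries and 18 libraries. Adjusted p is that of Benjamini and Hochberg over all genes tested, with a threshold of 0.05.

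Named genes were the 8 highest and 8 lowest log2 fold changes among protein-coding genes with adjusted p under the threshold, a mean of at least 5 CPM (reads scaled to the library total) in the higher group, and every treated library above or below every sNT8 library. The number was 5 and 5 for the direct comparisons and the difference between lines. Up to 4 members of each list with the smallest p were named as well, and a set of genes fixed in advance, among them AGO1, AGO2, DICER1, FAS, FASLG and TNFRSF10B in every comparison. Some genes that the rule names are not reported here, and the counts of results by alternative leave them out. Genes with a value near 0 in 1 of the lines were left out of the text on the difference between lines, and the lowest group mean allowed, 0.1 CPM, was chosen after the values were seen.

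The 29 gene lists hold 821 entries: p53 targets, integrated stress response, unfolded protein response, heat shock, interferon-stimulated, NF-kB and inflammatory, mitosis and G2, DNA replication, replication-dependent histones, proteasome, spliceosome, cytosolic ribosomal proteins, translation initiation factors, aminoacyl-tRNA synthetases, cholesterol biosynthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, hypoxia and glycolysis, NRF2 targets, extracellular matrix, epithelial, mesenchymal, apoptosis, RNA interference, CAG or CTG repeat disease loci, immediate early, leukocyte and endothelial markers, and a comparison list of CCT chaperonin, coatomer and RNA polymerase II subunits. Each was tested with camera (limma) with a preset correlation of 0.01, and again with an estimated correlation. The test fry of limma asks whether the genes of a set move 1 way on balance and does not compare them with other genes.

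Transcript sequences and 3' UTRs were those of GENCODE 29, which has 58275 of the 58395 identifiers, 58192 of them on the same chromosome and strand and 57523 with the same start and end. The oligonucleotide sequences are not given in the sources used here, so the seeds were read from the names. The tests on matches used 100000 permutations within 10 groups of 3' UTR length and 5 groups of GC content, and ranked all 4096 hexamers. A run was at least 6 CTG units, 18 bases. Ribosomal protein genes were compared with 10000 random lists drawn from the genes nearest in transcript length, GC content and level.

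The alternatives were TMM scaling, library totals alone, no filter, a stricter filter of 50 in 3 libraries, a pseudocount of 0.1, protein-coding genes alone, DESeq2 1.42.0 with its Wald test on the recovered reads, a null of 1.5-fold, a fold of at least 2, a block by replicate letter, and leaving out each replicate. Added after the data were seen were edgeR on the recovered reads with 9 or 6 libraries and the authors' deposited adjusted p. The procedure was tested on simulated data with known folds, made with the levels and spread of each of the 4 comparisons with sNT8. There limma recovered 51.5 to 58.5 percent of genes at a fold of 1.5, 66.7 to 81.2 percent at 2 and 96.9 to 100 percent at 4, and called 0.041 to 0.073 percent of unchanged genes. Few genes were changed in the simulations, as 21577 of 21810 were unchanged in that for HeyA8 sCAG. Many more were called in the real data, so these rates may not carry over. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used. The mitochondrially encoded list was not tested because its genes are listed at 0, and the leukocyte list was tested in PC3 only, since 2 of its genes were measured in HeyA8. No level of a gene on the Y chromosome was examined.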

Results

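RNA was measured in HeyA8, a human ovarian cancer cell line, and in PC3, a human prostate cancer cell line. Cells were transfected for 48 h with 10 nM of 1 of 3 short RNAs, named sNT8, sG5C and sCAG, and total RNA was sequenced. The series title describes short RNAs that induce DISE, a form of cell death, and the deposited tables set sNT8 as the reference for the other two. The 18 libraries form 6 groups of 3, lettered A to C. The sG5C libraries carry the name Mxy in their titles and sG5C in their treatment field, and the treatment field was used. The 2 library names given for each PC3 library have different prefixes, of which the HeyA8 libraries carry 1 in both, so whether the lines were prepared and sequenced together is not given in the sources used here. Every comparison with sNT8 is within a line. Library totals ran from 31232377 to 41384838 reads assigned to genes, and 31659 to 36188 genes had at least 1 read. The labels do not say that the replicates were separate cultures, so p-values of single genes measure the spread between these libraries only. The camera p-values compare the genes of a list with other genes under a preset correlation, so spread between libraries does not set them alone. After sG5C, other splits of the same libraries called up to 12 lists in each line, against 12 in HeyA8 and 10 in PC3. After sCAG they called up to 10 in HeyA8 and 11 in PC3, against 13 in each. Every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.29 to 7.26. All 13 genes of the mitochondrially encoded list were listed at 0 in every library, so that list was not measured.

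The comparison of sCAG with sNT8 in HeyA8 asked which transcripts changed with sCAG. All 36 measured mitosis and G2 genes fell, with a median log2 fold change of -5.78 (camera adjusted p = 4.66e-36, and adjusted p = 0.101 with an estimated correlation). The mitotic kinase gene CDK1 (ENSG00000170312, chromosome 10, 60778331 to 60794852, hg38) had 5225 ± 171 normalized counts with sNT8 and 31.8 ± 6.8 with sCAG (SD, n = 3 each), a 162-fold fall (log2 fold change -7.34 ± 0.12, SE; limma adjusted p = 2.3e-20). The proliferation gene MKI67 fell 108-fold and TOP2A, a DNA topoisomerase gene, fell 144-fold. Among the 8 genes with the largest falls under the rule for named genes, NEK2 fell 186-fold and PBK 176-fold. The log2 fold change of PIF1 was -7.66, and -8.34 without sCAG replicate B, and that of the kinetochore gene NUF2 was -7.26, and -6.44 without sCAG replicate B. FREM2, which encodes an extracellular matrix protein, fell from 521.5 ± 84.1 to 3.2 ± 5.5 normalized counts (SD, n = 3 each), with 2 of the 3 sCAG libraries at 0 and replicate B at 9.6. Its log2 fold change of -7.88 ± 1.11 (SE) was -9.02 without sCAG replicate B and -10.14 with a pseudocount of 0.1, so the size of its fall is uncertain.

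All 40 measured DNA replication genes also fell after sCAG in HeyA8, with a median log2 fold change of -2.25 (camera adjusted p = 5.80e-24, and adjusted p = 0.107 with an estimated correlation). RRM1, a ribonucleotide reductase subunit gene, fell 9.71-fold and MCM4, of the replicative helicase, 6.60-fold. Of 46 replication-dependent histone genes 44 fell and 2 rose, with a median of -4.40 (camera adjusted p = 7.11e-29, and adjusted p = 0.161 with an estimated correlation), and HIST1H3G fell 198-fold. Histone genes have near-identical copies, so the value of any one of them is uncertain. Of 28 integrated stress response genes 21 fell and 6 rose, with a median of -0.95 (camera adjusted p = 1.56e-05, and adjusted p = 0.161 with an estimated correlation). The largest falls among the 4 with the smallest p were in enzymes and carriers of amino acid metabolism, PCK2 by 13.3-fold, PSAT1 by 9.44-fold and SLC7A11 by 7.75-fold. Of 20 cytosolic aminoacyl-tRNA synthetase genes 18 fell and none rose, with a median of -0.81 (camera adjusted p = 1.55e-10, and adjusted p = 0.161 with an estimated correlation), and GARS fell 7.19-fold. Of 43 spliceosome genes 30 fell and 3 rose, with a median of -0.30 (camera adjusted p = 2.74e-05, and adjusted p = 0.519 with an estimated correlation).

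Genes of several other groups rose in HeyA8 after sCAG. Of 27 p53 target genes 24 rose and 3 fell, with a median of 0.75 (camera adjusted p = 4.06e-09, and adjusted p = 0.101 with an estimated correlation). TP53INP1 rose 13.4-fold and MDM2, the gene of the ubiquitin ligase of p53, 4.28-fold. Of 24 hypoxia and glycolysis genes 22 rose and none fell, with a median of 1.19 (camera adjusted p = 3.94e-12, and adjusted p = 0.232 with an estimated correlation), led by ADM at 9.62-fold and BNIP3 at 5.25-fold. Of 23 NF-kB and inflammatory genes 17 rose and 4 fell, with a median of 1.02 (camera adjusted p = 1.34e-04, and adjusted p = 0.161 with an estimated correlation), and IL6 rose 18.6-fold. Apoptosis regulators had 20 of 33 higher and 7 lower, with a median of 0.30 (camera adjusted p = 0.00379, and adjusted p = 0.144 with an estimated correlation), and the death receptor gene FAS rose 2.62-fold, from 1250 ± 73.8 to 3279 ± 51.2 normalized counts (SD, n = 3 each). Extracellular matrix genes had 22 of 37 higher and 12 lower (median 0.40, camera adjusted p = 0.00426, and adjusted p = 0.519 with an estimated correlation), and interferon-stimulated genes 19 of 32 higher and 10 lower (median 0.48, camera adjusted p = 0.0186, and adjusted p = 0.303 with an estimated correlation). The 77 cytosolic ribosomal protein genes passed the list test upward (43 higher, 11 lower, median 0.12, camera adjusted p = 0.00769, and adjusted p = 0.787 with an estimated correlation), but with scaling to library totals 20 were higher and 20 lower and the median was 0.00. Under the same rule the largest rises were those of IGFBP5 at 58.9-fold, SYT16 at 51.3-fold, FLG at 36.7-fold, ITGB8 at 28.0-fold and ANGPTL4 at 26.7-fold.

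Across all genes, 13041 of 21980 tested passed limma's threshold in HeyA8 after sCAG, 6440 higher and 6601 lower, and 13 of 27 lists passed camera's. Adjusted over the list alone, the counts of the called lists were the same except for the ribosomal protein genes, with 47 higher and 11 lower. With an estimated correlation no list was called. Scaling to library totals moved the median of all genes by -0.12 (log2) and gave 5094 genes higher and 7911 lower, and the median of the apoptosis regulators was then 0.18.

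**Figure D1:**
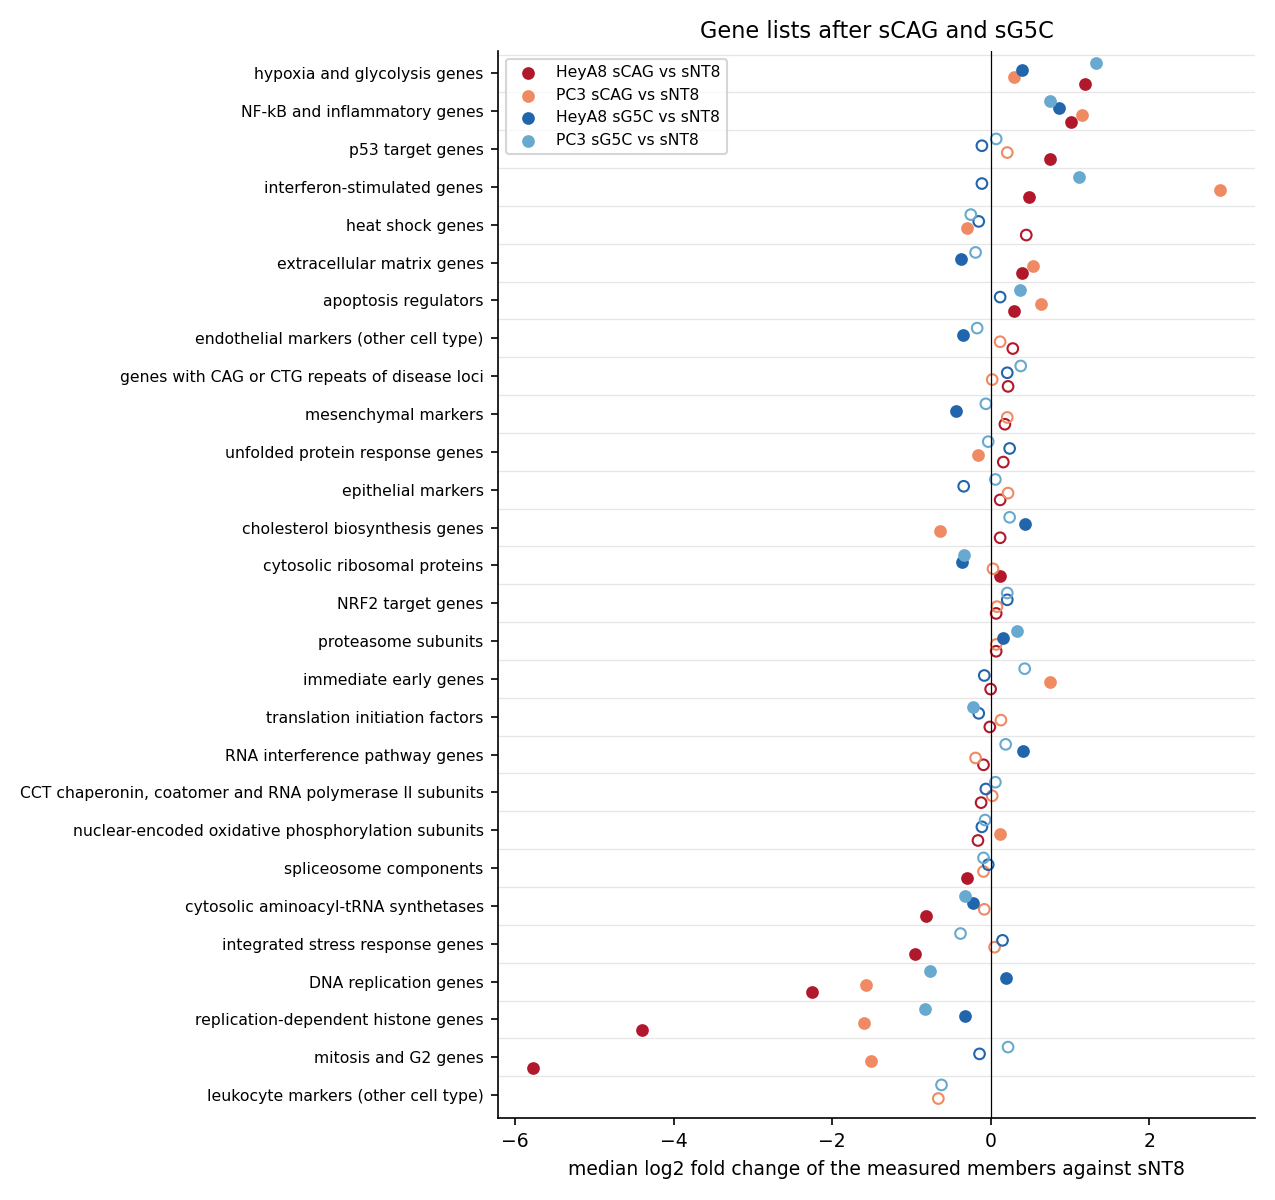
Median log2 fold change against sNT8 (x axis) of each fixed gene list (y axis) in HeyA8 and PC3 after sCAG and sG5C, 3 libraries per group, with filled points for lists with a camera adjusted p under 0.05 and open points for the others. The mitosis and G2 genes lie at -5.78 in HeyA8 and -1.51 in PC3 after sCAG, and the interferon-stimulated genes at 2.90 in PC3 after sCAG.

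The comparison of sG5C with sNT8 in HeyA8 asked which transcripts changed with sG5C. Of 77 cytosolic ribosomal protein genes 69 fell and none rose, with a median log2 fold change of -0.36 (camera adjusted p = 4.57e-12, and adjusted p = 0.742 with an estimated correlation), as with RPL13A, 1.70-fold lower. Of 37 extracellular matrix genes 22 fell and 8 rose, with a median of -0.38 (camera adjusted p = 0.00181, and adjusted p = 0.609 with an estimated correlation), and fibronectin, FN1, fell 7.30-fold and tenascin, TNC, 5.24-fold. Of 15 mesenchymal markers 10 fell and 1 rose, with a median of -0.44 (camera adjusted p = 0.00117, and adjusted p = 0.609 with an estimated correlation). SNAI2, a transcription factor of epithelial-mesenchymal transition, fell 10.1-fold, from 1531 ± 92.7 to 153.8 ± 38.3 normalized counts (SD, n = 3 each; log2 fold change -3.34 ± 0.16, SE; limma adjusted p = 2.7e-09). Under the rule for named genes the largest falls were those of PSG5, 24.3-fold, PTPN22, 15.2-fold, PSG4, 14.1-fold, INSC, 13.8-fold, TXNIP, 13.0-fold, and the receptor phosphatase gene PTPRU, 11.3-fold. PSG genes have near-identical copies, and their values are uncertain.

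Other groups rose in HeyA8 after sG5C. Of 23 NF-kB and inflammatory genes 15 rose and 1 fell (median 0.86, camera adjusted p = 1.39e-06, and adjusted p = 0.609 with an estimated correlation), and IL6 rose 5.11-fold. Of 25 cholesterol biosynthesis genes 17 rose and 3 fell (median 0.43, camera adjusted p = 8.53e-06, and adjusted p = 0.609 with an estimated correlation), among them INSIG1, a regulator of the pathway, at 2.92-fold and IDI1 at 2.35-fold. Of 14 RNA interference pathway genes 9 rose and 2 fell (median 0.41, camera adjusted p = 0.00795, and adjusted p = 0.609 with an estimated correlation). AGO2, whose protein cuts target RNA, went from 11102 ± 458 to 24423 ± 649 normalized counts (SD, n = 3 each), a 2.20-fold rise, DICER1 rose 1.75-fold, and DROSHA fell 2.23-fold. Hypoxia and glycolysis genes had 16 of 23 higher and 2 lower (median 0.39, camera adjusted p = 4.11e-05, and adjusted p = 0.609 with an estimated correlation), DNA replication genes 23 of 40 higher and 3 lower (median 0.19, camera adjusted p = 2.67e-04, and adjusted p = 0.795 with an estimated correlation), and proteasome subunits 16 of 32 higher and 1 lower (median 0.15, camera adjusted p = 0.0125, and adjusted p = 0.795 with an estimated correlation). Replication-dependent histone genes had 29 of 46 lower and 4 higher (median -0.32, camera adjusted p = 7.95e-05, and adjusted p = 0.795 with an estimated correlation), and aminoacyl-tRNA synthetases 14 of 20 lower and 2 higher (median -0.22, camera adjusted p = 0.00397, and adjusted p = 0.795 with an estimated correlation). Endothelial markers, a list of another cell type, had 5 of 7 lower and none higher (median -0.35, camera adjusted p = 0.0276, and adjusted p = 0.609 with an estimated correlation), with PECAM1 4.57-fold lower. Some genes of this list were well expressed in HeyA8 with sNT8. TIE1 had 398.55 to 404.53 CPM with sNT8 and 398.59 to 407.17 with sG5C. SYT11, a synaptotagmin gene (chromosome 1, 155859509 to 155885199), had the largest rise under that rule, 9.83-fold, from 130.5 ± 3.3 to 1299 ± 165 normalized counts (SD, n = 3 each), followed by MED12L at 9.19-fold and the receptor kinase gene MERTK at 8.19-fold. FAS was 1.58-fold lower.

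In this comparison 11735 of 22354 genes passed, 5496 higher and 6239 lower, and 12 of 27 lists. Adjusted over the list alone, the counts differed from these for the NF-kB genes (16 higher, 1 lower), histone genes (4 and 30), ribosomal protein genes (0 and 72), hypoxia genes (17 and 2) and RNA interference genes (9 and 3). With an estimated correlation no list was called, and scaling to library totals moved the median of all genes by 0.13 (log2), with 7425 genes higher and 4834 lower. With that scaling the medians of the aminoacyl-tRNA synthetases (-0.09, 10 lower and 3 higher), histone genes (-0.19), extracellular matrix genes (-0.25), ribosomal protein genes (-0.22) and endothelial markers (-0.22) were smaller in size, and those of the DNA replication genes (0.32) and proteasome subunits (0.29) larger.

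In PC3, sCAG against sNT8 gave a rise in interferon-stimulated genes. All 39 measured members rose, with a median log2 fold change of 2.90 (camera adjusted p = 3.97e-35, and adjusted p = 0.305 with an estimated correlation). The transcription factor genes STAT2 and IRF7 rose 6.17-fold and 5.17-fold. Under the rule for named genes the largest rises were those of the following genes. IDO1, an enzyme of tryptophan breakdown (ENSG00000131203, chromosome 8, 39902275 to 39928444), went from 12.3 ± 7.6 to 2149 ± 319 normalized counts (SD, n = 3 each), 189-fold higher (log2 fold change 7.56 ± 0.63, SE; limma adjusted p = 6.6e-04), and its log2 fold change was 6.93 without sNT8 replicate A. The chemokine genes CXCL10 and CXCL11 rose 97.0-fold and 82.9-fold, and CXCL9 was listed at 0 in all 3 sNT8 libraries and averaged 219.6 ± 56.5 normalized counts with sCAG (SD, n = 3). AIM2 and CASP1, the gene of the inflammatory caspase, had log2 fold changes of 6.52 and 6.17, and of 5.81 and 5.44 without sNT8 replicate A. The guanylate-binding protein genes GBP5 and GBP4 rose 88.4-fold and 87.6-fold, with uncertainty from reads shared between GBP copies. Of 22 NF-kB and inflammatory genes 19 rose and none fell (median 1.15, camera adjusted p = 5.05e-09, and adjusted p = 0.330 with an estimated correlation).

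Proliferation genes fell in PC3 after sCAG as well. All 40 DNA replication genes fell, with a median of -1.57 (camera adjusted p = 1.09e-33, and adjusted p = 0.0387 with an estimated correlation), MCM2 by 3.63-fold and RRM2 by 3.33-fold. All 36 mitosis and G2 genes fell, with a median of -1.51 (camera adjusted p = 6.86e-33, and adjusted p = 0.121 with an estimated correlation), MKI67 by 4.16-fold. Of 39 histone genes 35 fell and 2 rose (median -1.60, camera adjusted p = 1.26e-20, and adjusted p = 0.330 with an estimated correlation). Of 25 cholesterol biosynthesis genes 20 fell and none rose (median -0.64, camera adjusted p = 3.06e-08, and adjusted p = 0.375 with an estimated correlation), with MVK, of the mevalonate pathway, 1.75-fold lower. Heat shock genes had 10 of 16 lower and 2 higher (median -0.30, camera adjusted p = 6.67e-04, and adjusted p = 0.485 with an estimated correlation), and unfolded protein response genes 9 of 19 lower and 3 higher (median -0.16, camera adjusted p = 0.0257, and adjusted p = 0.523 with an estimated correlation). The latter call was lost without PC3 sNT8 replicate B. Extracellular matrix genes had 26 of 39 higher and 7 lower (median 0.53, camera adjusted p = 3.34e-06, and adjusted p = 0.305 with an estimated correlation), with the collagen gene COL12A1 3.09-fold higher and the collagen gene COL1A2 14.8-fold lower. Apoptosis regulators had 21 of 34 higher and 5 lower (median 0.63, camera adjusted p = 1.25e-06, and adjusted p = 0.121 with an estimated correlation), with FAS 2.80-fold higher. Immediate early genes had 16 of 20 higher and 1 lower (median 0.75, camera adjusted p = 2.87e-06, and adjusted p = 0.330 with an estimated correlation), and hypoxia and glycolysis genes 15 of 24 higher and 3 lower (median 0.29, camera adjusted p = 0.00129, and adjusted p = 0.523 with an estimated correlation). The 48 nuclear-encoded oxidative phosphorylation genes passed upward (23 higher, 4 lower, median 0.12, camera adjusted p = 0.0383, and adjusted p = 0.640 with an estimated correlation), but the median was -0.05 with scaling to library totals, and the call was lost without PC3 sNT8 replicate C or PC3 sCAG replicate A. Besides COL1A2, the largest falls under that rule included those of C4orf48, 23.9-fold, PRKCSH and BRI3BP, 13.8-fold each, and LRRC59, 13.7-fold, from 13812 ± 283 to 1006 ± 91.1 normalized counts (SD, n = 3 each).

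In this comparison 11689 of 23130 genes passed, 6344 higher and 5345 lower, and 13 of 28 lists. Adjusted over the list alone, the counts differed for the NF-kB genes (20 higher, 0 lower), unfolded protein response genes (3 and 10), cholesterol genes (1 and 20), extracellular matrix genes (26 and 8) and immediate early genes (17 and 2). The DNA replication genes were the only list called with an estimated correlation. Scaling to library totals moved the median of all genes by -0.17 (log2) and gave 4136 genes higher and 7997 lower. With that scaling the hypoxia and glycolysis genes had 10 higher and 5 lower and a median of 0.12, and the medians of the heat shock genes (-0.47) and unfolded protein response genes (-0.33) were larger in size.

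**Figure D2:**
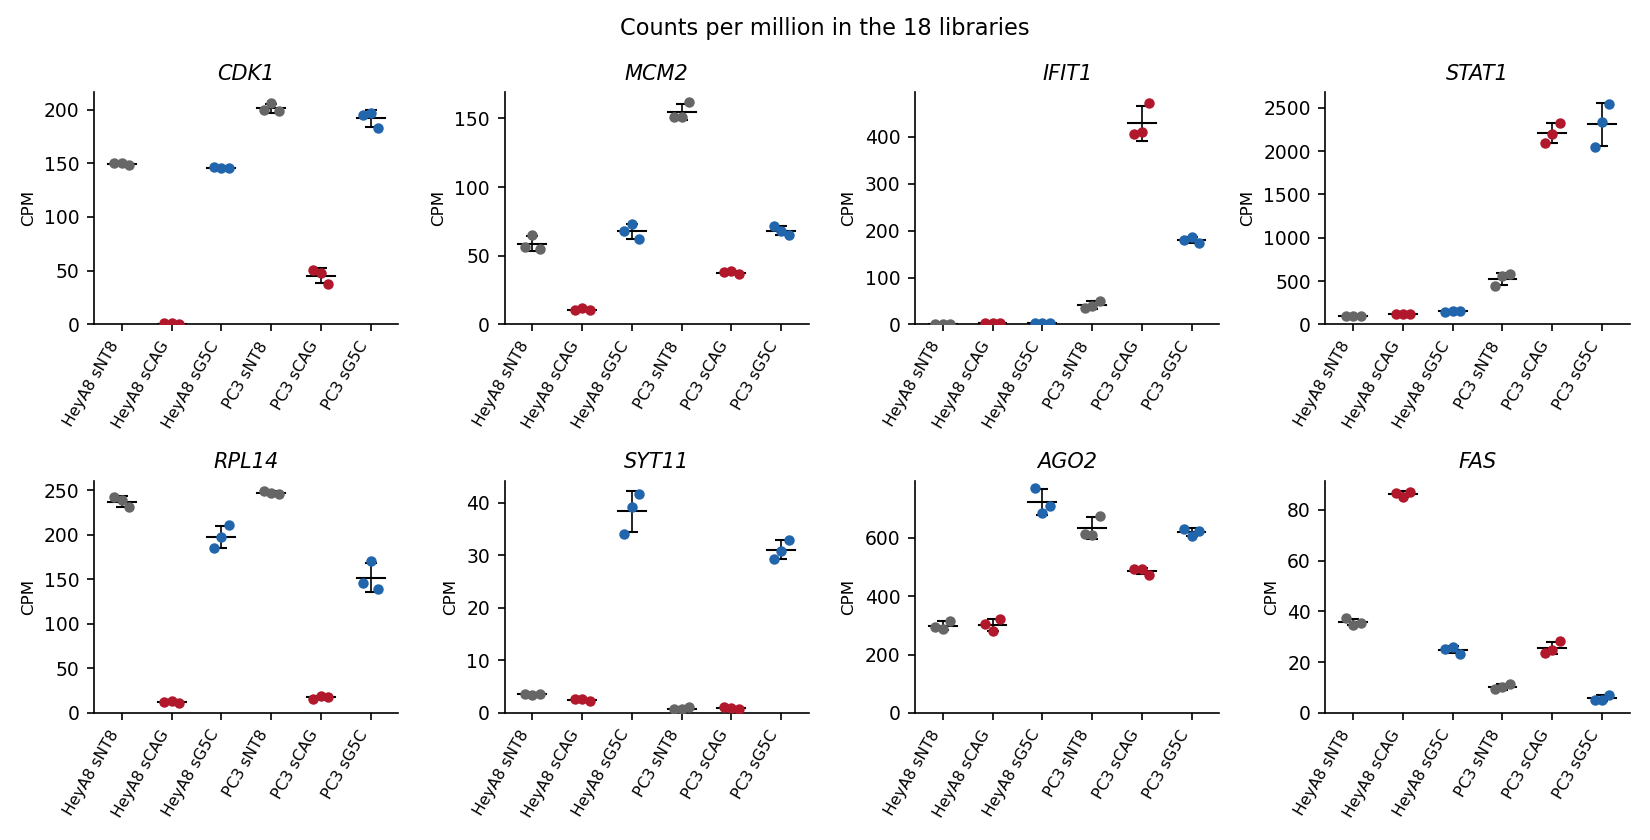
CPM (y axis) of 8 genes, chosen after their values were seen, in the 6 groups (x axis), with libraries as points, means as lines and SD as bars, n = 3 per group. CDK1 averages 149.6 in HeyA8 with sNT8 and 0.838 with sCAG, and IFIT1 averages 41.5 in PC3 with sNT8, 180.3 with sG5C and 429.2 with sCAG.

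The comparison of sG5C with sNT8 in PC3 gave rises in hypoxia, interferon and inflammatory genes. Of 24 hypoxia and glycolysis genes 22 rose and none fell, with a median log2 fold change of 1.33 (camera adjusted p = 3.78e-18, and adjusted p = 0.539 with an estimated correlation), with EGLN3, an oxygen-sensing prolyl hydroxylase gene, 7.11-fold and the glucose transporter gene SLC2A1 4.88-fold higher. Of 39 interferon-stimulated genes 36 rose and none fell, with a median of 1.11 (camera adjusted p = 3.78e-18, and adjusted p = 0.612 with an estimated correlation), and IFIT2 rose 8.55-fold. Of 22 NF-kB and inflammatory genes 13 rose and 1 fell (median 0.75, camera adjusted p = 0.00129, and adjusted p = 0.539 with an estimated correlation), with BIRC3 15.8-fold higher. Of 33 apoptosis regulators 21 rose and 10 fell (median 0.37, camera adjusted p = 0.0138, and adjusted p = 0.539 with an estimated correlation). Proteasome subunits had 20 of 32 higher and none lower (median 0.33, camera adjusted p = 1.90e-05, and adjusted p = 0.806 with an estimated correlation). SYT11 again had the largest rise under the rule for named genes, 38.5-fold, from 26.8 ± 7.1 to 1048 ± 33.3 normalized counts (SD, n = 3 each; log2 fold change 5.27 ± 0.15, SE; limma adjusted p = 4.2e-21), and ANGPTL4 rose 33.5-fold, ACHE 25.6-fold and EGR1 16.1-fold.

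Other groups fell in PC3 after sG5C. Of 40 DNA replication genes 37 fell and 1 rose, with a median of -0.77 (camera adjusted p = 1.87e-13, and adjusted p = 0.612 with an estimated correlation), and E2F1, a transcription factor of S phase entry, fell 4.54-fold. Of 39 histone genes 34 fell and 3 rose (median -0.83, camera adjusted p = 5.36e-10, and adjusted p = 0.806 with an estimated correlation). Of 77 ribosomal protein genes 57 fell and 1 rose (median -0.33, camera adjusted p = 1.99e-07, and adjusted p = 0.806 with an estimated correlation), with RPLP0 1.97-fold lower. Translation initiation factors had 19 of 32 lower and 4 higher (median -0.22, camera adjusted p = 0.0207, and adjusted p = 0.806 with an estimated correlation), with EIF5A 8.20-fold lower, and this call was lost without PC3 sG5C replicate C. Aminoacyl-tRNA synthetases had 14 of 20 lower and 4 higher (median -0.32, camera adjusted p = 0.0126, and adjusted p = 0.806 with an estimated correlation). Under the same rule the chromatin gene HMGA1 fell most, 19.4-fold, from 46120 ± 696 to 2385 ± 280 normalized counts (SD, n = 3 each), followed by COL1A2 at 17.2-fold, ARHGDIA at 13.1-fold, TFEC at 11.3-fold and PLCXD3 at 11.2-fold. FAS was 1.73-fold lower. Of 23731 genes 13737 passed, 6784 higher and 6953 lower, and 10 of 28 lists passed, none of them with an estimated correlation. Adjusted over the list alone, the counts differed for the interferon genes (37 higher, 0 lower), NF-kB genes (14 and 1), proteasome subunits (21 and 0), ribosomal protein genes (2 and 58), translation initiation factors (5 and 19) and hypoxia genes (23 and 0).

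The direct comparison of sCAG with sG5C was fitted with edgeR on reads recovered from the deposited values. In HeyA8, CCND2, a cyclin gene of G1 phase, averaged 70.4 ± 0.19 CPM (reads scaled to the library total) with sCAG and 0.71 ± 0.06 with sG5C (SD, n = 3 each), a 117-fold difference (log2 fold change 6.87 ± 0.10, SE; edgeR adjusted p = 2.9e-33). HJURP, a centromere chaperone gene, was 201-fold lower with sCAG, and PBK 291-fold lower. In PC3, CXCL11 was 73.1-fold and TFEC 47.4-fold higher with sCAG, while SYT11 was 29.2-fold lower. FAS was 4.13-fold higher with sCAG than with sG5C in HeyA8 and 4.83-fold higher in PC3. AGO2 was 2.02-fold lower with sCAG in HeyA8 and 1.17-fold lower in PC3. In HeyA8, 15147 of 23238 genes differed, 7385 higher and 7762 lower with sCAG, and in PC3 15430 of 24618, 7780 higher and 7650 lower. Scaling to library totals moved the median of all genes by -0.25 (log2) in HeyA8 and -0.12 in PC3, and gave 5312 genes higher and 10431 lower in HeyA8.

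Genes changed by both short RNAs were counted within each line. In HeyA8, 1795 genes rose with both (independent lists of these sizes would share 1471) and 2637 fell with both (1932), 4432 in all, while 3537 genes moved in opposite directions. In PC3, 2562 rose with both (1718) and 2403 fell with both (1646), 4965 in all, while 3150 moved in opposite directions. For opposite directions, here and across the cell lines below, the number expected of independent lists was not worked out. The excess within a line is therefore not shown to be confined to genes that moved the same way. Both comparisons of a line use the same 3 sNT8 libraries, which cannot be split with 2 in each part, so part of the excess can come from them. In 20 simulations of unchanged groups against those libraries, the mean number of genes called alike was 0 in HeyA8 and 0.05 in PC3. Unchanged groups give almost no calls, so this count does not show how much the shared libraries add among changed genes. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.106 in HeyA8 and 0.234 in PC3, against 0.509 and 0.532 in the simulations. The covariance was 0.0695 in HeyA8 and 0.135 in PC3, against 0.0246 and 0.0290 in the simulations. Leaving out 1 replicate it ran from 0.0632 to 0.1002 in HeyA8, highest without sNT8 replicate C, and from 0.131 to 0.161 in PC3, and by DESeq2, which tested more genes than the simulations hold, it was 0.368 in HeyA8 and 0.462 in PC3 with correlations of 0.271 and 0.355, so the size of a shared effect is not given.

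Across the cell lines, which share no libraries, 3112 genes rose with sCAG in both (independent lists would share 1727) and 2798 fell in both (1460), 5910 in all, while 1763 moved in opposite directions. With sG5C, 3056 rose in both (1528) and 3605 fell in both (1756), 6661 in all, while 1320 moved in opposite directions. FAS was higher after sCAG and lower after sG5C in both lines. Its effects did not differ detectably between the lines (interaction log2 0.11 ± 0.11, SE, edgeR adjusted p = 0.49 for sCAG, and -0.10 ± 0.13, adjusted p = 0.59 for sG5C). SYT11 was the gene with the largest rise after sG5C in each line under the rule for named genes.

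The effect of each short RNA was also compared between the lines with an interaction term, PC3 minus HeyA8. For sCAG, 10051 of 27105 genes differed, 5996 with a higher effect in PC3 and 4055 with a lower one. All 36 mitosis and G2 genes fell further in HeyA8 (median difference 4.04, camera adjusted p = 5.41e-311, and adjusted p = 2.21e-06 with an estimated correlation), and 34 of 39 interferon-stimulated genes had a higher effect in PC3 (median difference 2.64, camera adjusted p = 2.12e-38, and adjusted p = 0.0337 with an estimated correlation). Filaggrin, FLG, rose in HeyA8 from 0.25 ± 0.09 to 8.93 ± 0.96 CPM and fell in PC3 from 12.6 ± 0.98 to 3.98 ± 0.04 (SD, n = 3 each), and the hyaluronan synthase gene HAS2 rose from 0.95 ± 0.30 to 15.2 ± 2.53 and fell from 14.5 ± 0.66 to 6.09 ± 0.47. For sG5C, 8893 genes differed, 4949 with a higher effect in PC3 and 3944 with a lower one. Of 40 DNA replication genes 39 had a lower effect in PC3 (median difference -0.93, camera adjusted p = 8.29e-44, and adjusted p = 0.0148 with an estimated correlation). The potassium channel gene KCNK3 fell in HeyA8 from 26.7 ± 0.48 to 4.26 ± 0.22 CPM and rose in PC3 from 0.13 ± 0.09 to 1.45 ± 0.31 (SD, n = 3 each), few reads in PC3.

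Protein-coding genes were grouped by sequence as well. The name sG5C was read as GGGGGC, whose complement in a transcript is GCCCCC, and the name sCAG as a CAG repeat whose complement is CTG. The classes by number of sites were chosen after the values were seen and were not matched for 3' UTR length or GC content. After sG5C in HeyA8, the mean log2 fold change was -0.02 ± 0.007 (SE across 9558 genes) without GCCCCC in the annotated 3' UTR, -0.16 ± 0.016 with 1 site (2168 genes), -0.30 ± 0.026 with 2 (869 genes) and -0.47 ± 0.034 with 3 or more (686 genes). In PC3 the means were 0.09 ± 0.008, -0.09 ± 0.019, -0.17 ± 0.031 and -0.39 ± 0.039. After sCAG the means of the same classes in HeyA8 were -0.16 ± 0.011, -0.05 ± 0.021, 0.01 ± 0.033 and 0.04 ± 0.035, and in PC3 they were 0.03 ± 0.008, 0.04 ± 0.016, 0.04 ± 0.026 and -0.03 ± 0.023. Within strata of 3' UTR length and GC content, genes with a site differed from the others in HeyA8 by -0.23 after sG5C and 0.0201 after sCAG. In PC3 these differences were -0.251 and 0.0107. After sCAG, 64 of 86 genes with a run of at least 6 CTG units anywhere in the transcript fell in HeyA8 and 8 rose, and in PC3 70 of 91 fell and 7 rose. Among the genes without such a run, 5076 of 13310 fell in HeyA8 and 3676 of 13867 in PC3. RPL14, a ribosomal protein gene of chromosome 3 (40457292 to 40468587) with 10 CTG units in its coding sequence, fell from 237.2 ± 5.93 to 12.6 ± 1.23 CPM in HeyA8 and from 246.7 ± 1.92 to 17.4 ± 2.14 in PC3 (SD, n = 3 each). Of the 8 genes named for the largest falls in PC3 after sCAG, BRI3BP, C4orf48 and LRRC59 are among those that hold such a run, and of the 8 in HeyA8 FREM2 does. Genes are not replicates, so the standard errors across genes describe these libraries.

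**Figure D3:**
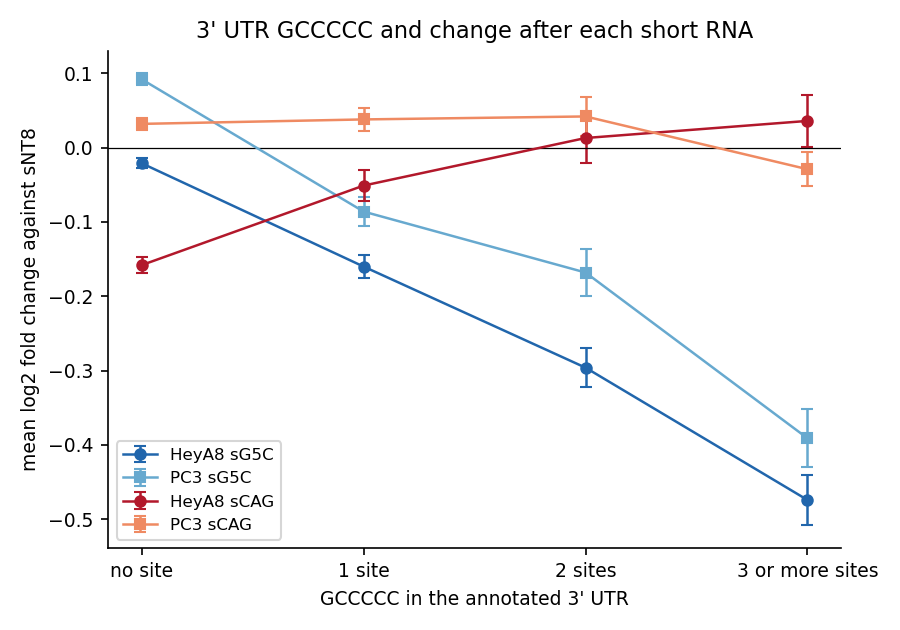
Mean log2 fold change against sNT8 (y axis) of protein-coding genes by the number of GCCCCC sites in the annotated 3' UTR (x axis) in HeyA8 and PC3 after each short RNA, with SE across genes, which are not replicates, as bars. In HeyA8 the mean goes from -0.02 without a site to -0.47 with 3 or more after sG5C, and from -0.16 to 0.04 after sCAG. The classes were not matched for 3' UTR length or GC content. Within strata of these, genes with a site differed from the others in HeyA8 by -0.23 after sG5C and 0.0201 after sCAG.

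**Figure D4:**
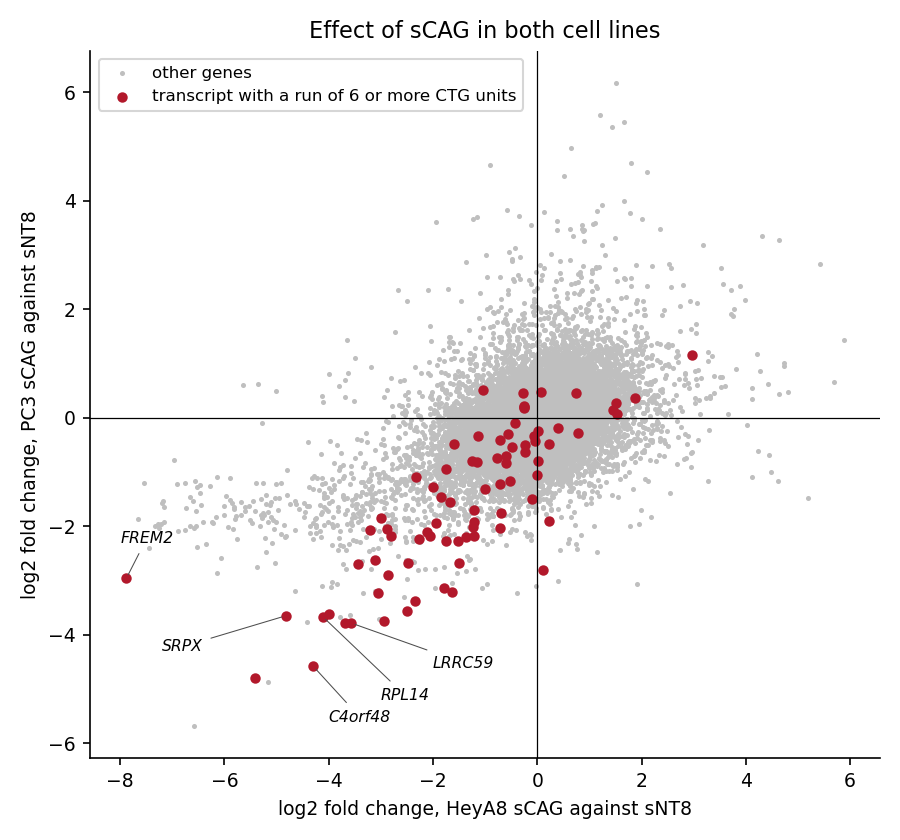
Log2 fold change after sCAG in HeyA8 (x axis) and PC3 (y axis) of each gene tested in both lines (points), with genes that hold a run of at least 6 CTG units marked. The labelled genes were chosen after their values were seen, and RPL14 lies at -4.12 in HeyA8 and -3.66 in PC3.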

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

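In this part the tests chosen after the result was seen are those on size factors, on a few genes taking more of the reads, on leukocytes and on other splits of the libraries, and the lowest group mean of 0.1 CPM for named genes. The results below stood out because a test of the difference itself (PC3 minus HeyA8, interaction term) passed its threshold. For sCAG 10051 genes differed between the lines and for sG5C 8893. For sCAG, mitosis and G2 genes had a median difference of 4.04 (log2), histone genes 3.00, interferon-stimulated genes 2.64, integrated stress response genes 1.08, immediate early genes 0.90, aminoacyl-tRNA synthetases 0.76, DNA replication genes 0.66, spliceosome components 0.29, oxidative phosphorylation subunits 0.24 and apoptosis regulators 0.12. Hypoxia and glycolysis genes had -0.90, heat shock genes -0.79, cholesterol biosynthesis genes -0.52, p53 targets -0.51 and unfolded protein response genes -0.18. With an estimated correlation, mitosis (camera adjusted p = 2.21e-06), p53 (1.86e-04), integrated stress response (0.0194) and interferon-stimulated genes (0.0337) still differed.

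For sG5C, interferon-stimulated genes had a median difference of 1.36, hypoxia and glycolysis genes 0.92, extracellular matrix genes 0.47, mitosis and G2 genes 0.30, proteasome subunits 0.24 and apoptosis regulators 0.22. DNA replication genes had -0.93, histone genes -0.47, cholesterol biosynthesis genes -0.24, unfolded protein response genes -0.23 and integrated stress response genes -0.18. Only DNA replication genes still differed with an estimated correlation (camera adjusted p = 0.0148). The differences of single genes were -6.75 for FLG, -5.19 for HAS2, -0.48 for DICER1 and -0.32 for AGO2 with sCAG. With sG5C they were 6.28 for KCNK3, 5.70 for PTPN22, 5.63 for LBH, -4.56 for SLC7A8, -1.09 for AGO2, -0.94 for TNFRSF10B, -0.46 for DICER1 and -0.44 for AGO1. KCNK3, PTPN22 and LBH averaged 0.13 to 0.17 CPM in PC3 with sNT8 and SLC7A8 0.10 in HeyA8, so their differences rest on few reads in 1 line. The difference was 6.99 for KCNK3 without PC3 sNT8 replicate A and 6.35 for LBH without PC3 sNT8 replicate C.

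Mitosis and G2 genes fell further after sCAG in HeyA8 than in PC3. The interaction test used TMM scaling and not the authors' size factors. Those factors are argued against as the whole cause of the gap between the list medians, -5.78 in HeyA8 and -1.51 in PC3. Scaled to library totals, the medians lay 4.22 apart. A few genes taking more of the reads is argued against as well, since the share of reads outside the 10 highest genes fell by 0.064 (log2) in HeyA8, far less than the list. A difference between the cell lines in how they respond stays open as a hypothesis and was not tested. Less short RNA in PC3 cells gets no support from the genes with runs of at least 6 CTG units, which lay further below the other genes in PC3 (-1.59) than in HeyA8 (-1.27), though that difference between the lines was not tested and the amount in the cells was not measured.

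Interferon-stimulated genes rose further after sCAG in PC3 than in HeyA8. The authors' size factors are argued against as the whole cause of the gap between the list medians, 0.48 in HeyA8 and 2.9 in PC3. Scaled to library totals, the medians lay 2.37 apart. RNA from leukocytes is argued against, since the 4 of 13 leukocyte markers measured in PC3 had a median log2 fold change of -0.66, and PTPRC had 2, 1 and 0 reads in the sCAG libraries. The labels name no sort, and PC3 also expresses LCP1, CSF1R, CORO1A and LYZ without sCAG. A response of PC3 cells to the short RNA stays open as a hypothesis and was not tested. More short RNA in PC3 cells gets no support from the mitosis and G2 genes, which fell less there than in HeyA8. The genes with runs of at least 6 CTG units go the other way, since they lay further below the other genes in PC3 (-1.59) than in HeyA8 (-1.27). That difference was not tested and the amount in the cells was not measured. More short RNA in PC3 cells therefore stays open.

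Ribosomal protein genes fell after sG5C in both lines. The authors' size factors are argued against as the whole cause, since the median was -0.22 in HeyA8 and -0.38 in PC3 when scaled to library totals. Gene length and GC content are argued against as far as the matching goes, with list medians of -0.355 in HeyA8 and -0.328 in PC3. The share of random lists with a median as low was 0.01 percent in each line, the smallest value that 10000 lists can give. The matching was incomplete, with a median transcript length of 1017 for the list and 1605 and 1604 for its pools in HeyA8 and PC3, and a median level of 297.3 CPM against 131.1 and 127.9. An effect of sG5C on these transcripts stays open as a hypothesis and was not tested.

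Other splits of the libraries were used to ask whether chance can be excluded. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real counts of genes were 13041 (HeyA8 sCAG), 11735 (HeyA8 sG5C), 11689 (PC3 sCAG), 13737 (PC3 sG5C), 15147 (sCAG against sG5C in HeyA8) and 15430 (PC3), and the highest of the other splits 0 in each. In each of these, 1 of 10 splits, the real one, gave as many genes. The real counts of lists were 13, 12, 13 and 10 in the order of the first 4, and the highest others 10, 12, 11 and 12, with 1, 2, 1 and 4 of the 10 splits giving as many. For genes called in both lines, 1 of 100 draws, the real one, gave as many for sCAG (5910, highest other 0) and for sG5C (6661, highest other 0), but every other split of a line called 0 genes, so these draws follow from the splits within each line and do not test the sharing. For the difference between lines, 1 of 40 draws, the real one, gave as many for sCAG (10051, highest other 2362) and for sG5C (8893, highest other 1310). The other draws mix the groups of each line, which removes the effects of the short RNAs. They do not test whether an effect differs between the lines, so they do not exclude chance for that difference.

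Genes called for both short RNAs were also counted in draws with the 9 libraries of a line scaled together. As many came from 2 of 100 draws in HeyA8 (4411, highest other 6738) and 3 of 100 in PC3 (4972, highest others 7120 and 7070), the real one among them. The other draws mix the groups of a line, which removes each short RNA's own effect, so they do not test the sharing or exclude chance for it. The other draws that gave more each kept 1 short RNA's 3 libraries whole as the control, sCAG in HeyA8 and sG5C in PC3, against mixtures of the other two groups. That points to a structure of the samples, namely the distance of that short RNA from the other two groups.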

How the results depend on the processing

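The alternatives chosen after the data were seen were edgeR with 9 or 6 libraries and the authors' deposited adjusted p. Across the 4 comparisons with sNT8, edgeR with 9 libraries gave 13103, 11978, 11468 and 14052 genes (HeyA8 sCAG, HeyA8 sG5C, PC3 sCAG, PC3 sG5C), edgeR with 6 libraries 13064, 11945, 11609 and 13772, the deposited adjusted p 12623, 11399, 11370 and 13397, and the DESeq2 Wald test 11841, 10346, 10189 and 12499. Against a null of a 1.5-fold change, the counts were 4144, 2391, 2434 and 4156, and 7330 and 7106 for sCAG against sG5C in HeyA8 and PC3. The stricter null explains this, since fewer genes differ by more than that fold. With a fold of at least 2, genes called for both short RNAs were 493 in HeyA8 and 634 in PC3, and genes called in both lines 912 for sCAG and 1060 for sG5C.

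Without 1 replicate the counts ran from 12168 to 12478, 10739 to 11181, 10539 to 11313 and 12885 to 13340 for the 4 comparisons, 14444 to 14735 and 14468 to 14939 for the direct ones, and 9258 to 9693 and 8192 to 8604 for the difference between lines. Those shared ran from 3924 to 4287 and 4360 to 4825 for both short RNAs, and 5513 to 5846 and 6195 to 6559 for both lines.

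Lists called with an estimated correlation numbered 0, 0, 1 and 0, against 13, 12, 13 and 10 with the preset one. The test fry called 21, 18, 22 and 20, and reversed the direction of the CCT chaperonin, coatomer and RNA polymerase II genes in PC3 after sG5C (adjusted p = 0.0373), whose mean of -0.12 and median of 0.06 differ in sign. Leaving out 1 replicate gave 13 to 13, 12 to 15, 12 to 14 and 9 to 12 lists. The unfolded protein response call in PC3 after sCAG was lost without sNT8 B (adjusted p = 0.0508), the oxidative phosphorylation call without sNT8 C (0.107) or sCAG A (0.0928), and the translation initiation call after sG5C without sG5C C (0.0582). Other lists, not called with all libraries, passed without 1 replicate: after sG5C in HeyA8, mitosis, CCT, translation initiation and integrated stress response genes, after sCAG in PC3 mesenchymal markers, and after sG5C in PC3 integrated stress response, heat shock and immediate early genes (adjusted p = 0.0176 to 0.0493).

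The call of AGO2 in HeyA8 after sCAG (log2 0.13) was lost with library totals (0.01), and without sNT8 B (0.10), sCAG A (0.13) or sCAG C (0.08) at folds of the same sign. The cause was not tested. Over the alternatives, without the genes not reported here, 9730 results of named genes were the same, 194 weaker, 10 stronger, 5 moved and 0 reversed, and for list tests 979, 53, 55, 12 and 1.

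Whether letters pair the libraries is not given in the sources used here. Deviations correlated best with the own letter in every comparison except HeyA8 sG5C A and C, at -0.036 to 0.131, a hint too weak to pair them. A block by letter gave 13430, 11661, 12258 and 14230 genes, 15193 and 15777 for the direct comparisons, 10339 and 9226 for the difference between lines, and 14, 12, 13 and 11 lists. At a simulated fold of 1.5, with far fewer genes changed than were called in the real data, limma recovered 51.5 to 58.5 percent of genes. The part of depth in this was not tested.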

Other observations

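In this part the tests of CTG runs within strata of transcript length and GC content, the classes by number of sites and the naming of genes with a run outside the rule were chosen after the results were seen, and the other match tests before. The death receptor gene TNFRSF10B was 1.69-fold higher after sCAG in HeyA8 and 1.49-fold higher in PC3, and after sG5C 1.41-fold higher in HeyA8 and 1.38-fold lower in PC3. AGO1, another Argonaute gene, was 1.42-fold lower after sCAG in HeyA8 and 1.59-fold lower in PC3. DROSHA, which encodes the nuclease that cuts primary microRNAs, was 3.18-fold lower after sG5C in PC3, from 5420 ± 149 to 1704 ± 70.5 normalized counts (SD, n = 3 each). FASLG, the ligand of FAS, was too low to test, at 5.5 ± 4.8 normalized counts in HeyA8 with sNT8 and 3.5 ± 3.6 with sCAG (SD, n = 3 each). The nuclear RNA MALAT1 made up 1.09 to 1.24 percent of reads in HeyA8 with sNT8, 2.09 to 2.20 percent with sG5C and 3.44 to 3.49 percent with sCAG, and in PC3 0.61 to 0.65, 1.04 to 1.36 and 0.91 to 0.98 percent.

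Lists that passed in no comparison with all libraries were the following, in the order HeyA8 sCAG, HeyA8 sG5C, PC3 sCAG and PC3 sG5C. NRF2 targets had medians of 0.07, 0.21, 0.08 and 0.21 (camera adjusted p = 0.183, 0.392, 0.140 and 0.141), with a mean of -0.01 in HeyA8 after sG5C. Epithelial markers had 0.12, -0.34, 0.22 and 0.06 (camera adjusted p = 0.484, 0.139, 0.277 and 0.564), with a mean of -0.22 in HeyA8 after sCAG. The CAG or CTG repeat disease loci had 0.22, 0.21, 0.02 and 0.38 (camera adjusted p = 0.537, 0.214, 0.80 and 0.436), with a mean of -0.11 in PC3 after sCAG. The CCT chaperonin, coatomer and RNA polymerase II subunits had -0.12, -0.06, 0.02 and 0.06 (camera adjusted p = 0.129, 0.10, 0.730 and 0.852), and in HeyA8 after sG5C they passed without sNT8 replicate C (0.0482) or sG5C replicate B (0.0368). Leukocyte markers in PC3 had -0.66 after sCAG and -0.62 after sG5C (camera adjusted p = 0.0840 and 0.50). Mitosis and G2 genes, which passed after sCAG, did not pass after sG5C and had -0.14 in HeyA8 and 0.22 in PC3 (camera adjusted p = 0.0669 and 0.151), but passed downward in HeyA8 without sNT8 replicate C (0.0207) or sG5C replicate B (0.0398).

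Genes lower after sG5C may hold matches to a GGGGGC seed, a hypothesis taken from the name. Within strata of 3' UTR length and GC content, genes with GCCCCC had a mean log2 fold change lower than others by a difference of -0.23 in HeyA8 and -0.251 in PC3 (permutation p = 2.0e-05 in each, the smallest they can give), and GCCCCC ranked 1 among all hexamers in each line. After sCAG the difference was 0.0201 in HeyA8 (permutation p = 0.383), though 0.138 without strata (permutation p = 2.0e-05), and 0.0107 in PC3 (permutation p = 0.540). Of the 8 genes named for the largest falls after sG5C in PC3, HMGA1, ARHGDIA, SDC1 and SLC7A8 hold the site, and of the 7 searched in HeyA8 SIGLEC15 does. Among all genes searched, 3887 of 13969 in PC3 and 3723 of 13281 in HeyA8 hold it, so these few named genes add little. Among genes without a site 32.4 percent fell in HeyA8, so a site in the 3' UTR searched is not needed for a fall. The rest of the transcript and other transcripts of a gene were not searched for it.

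Genes lower after sCAG may hold 3' UTR matches to a CAG-repeat guide (CTGCTG, TGCTGC or GCTGCT), and the test required this in both lines. It failed as written, with a difference of -0.015 in HeyA8 (permutation p = 0.5235) and -0.099 in PC3 (permutation p = 2.0e-05, the smallest they can give). Among all hexamers ranked by the difference, GCTGCT was 1 in PC3 and 48 in HeyA8, TGCTGC 2 and 174, and CTGCTG 26 and 1008. Ranked by the difference over its standard error they were 1 and 13, 2 and 77, and 7 and 867. Looking at the lines apart was decided after this result was seen.

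Genes lower after sCAG may also hold long CTG runs. Genes with a run of at least 6 units had a mean log2 fold change lower than the others by a difference of -1.267 in HeyA8 and -1.592 in PC3 (permutation p = 2.0e-05 in each, the smallest they can give), and within strata of transcript length and GC content -1.31 and -1.58. After sG5C the difference was -0.0575 in HeyA8 (permutation p = 0.443) and 0.0983 in PC3 (permutation p = 0.262). With the run in the coding sequence, 50 of 64 genes fell in HeyA8 and 58 of 68 in PC3, with the run in the 5' UTR 9 of 10 and 6 of 11, and with the run in the 3' UTR 5 of 12 and 6 of 12. Differences by position were not tested. Among protein-coding genes searched, 64 and 70 with a run fell, and 5076 and 3676 without one, so runs leave most of the falls after sCAG unexplained.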
